A study of Xenopus tropicalis with 11 samples.

How the data were processed

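The data are ChIP-seq peak lists from whole Xenopus tropicalis embryos (Nigerian A strain) at the early gastrula, stage 10.5. At this stage the Spemann-Mangold organizer lies above the dorsal lip. Per the labels, each chromatin sample came from 2000 to 3000 fixed embryos and was sequenced on an Illumina GAIIx. The 11 samples are 7 immunoprecipitated libraries and 4 input controls. The immunoprecipitated libraries comprise 3 homeodomain transcription factors (Otx2, Lim1, also called Lhx1, and Gsc, goosecoid), the corepressor TLE, the coactivator and acetyltransferase p300, and the histone marks H3K4me1 and H3K27ac. Otx2 and Lim1 share an input library, as do TLE and p300, and H3K4me1 and H3K27ac. Gsc has an input of its own. Only the 7 peak lists were analysed here, so the inputs entered no calculation.

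MACS2 and deepTools are named, without versions, in the submitters' processing notes. The aligner, the genome build and the read filters are not given in the sources used here. The Gsc, TLE and p300 lists are in narrow-peak layout and the other 4 in broad-peak layout, so widths and fold values were compared within a list and not between these layouts. Each deposited line gives a fold enrichment, a ratio of the peak's signal to the local background as MACS2 estimates it. Each line also gives a −log10 p and a −log10 q as deposited by the authors. The deposited score is 10 times the −log10 q without its decimals, which was checked on every line (largest difference 1). The narrow lists hold the summit's offset from the start of the interval, as the authors deposited it. The lowest −log10 q was 1.30 in the p300 list and 1.00 in the Otx2 list, so the broad lists admit weaker peaks. Fold and q are the authors' own values and served only to describe, rank, filter or stratify peaks, except where ranks of fold were correlated across shared regions.

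The narrow lists repeat an interval for each of its summits. Such lines were reduced to 1 interval, represented by its summit of highest fold. The coordinates run over 10 chromosomes and 4555 unplaced scaffolds. The gene table supplied for names uses the assembly UCB_Xtro_10.0, in which the last gene lay over 1 Mb past the last peak on all 10 of the 10 chromosomes compared. The lists were therefore treated as lying on another build that is not named, and regions are given by the coordinates of the lists alone, counted from 1. The planned analyses of gene lists, sequence motifs and distances to transcription start sites need a genome or annotation of that build and were not run. For the same reason no region is assigned to a gene, exon or intron.

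There is 1 library per antibody, so no replicate error can be given. All tests compare these lists with each other, peaks are not biological replicates, and intervals cover counting error only. Read depth is unknown from peak lists. A longer list can reflect deeper sequencing or a stronger antibody as well as more binding. The embryo was taken whole, so peaks of 2 libraries at 1 place need not come from the same cells.

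Peaks were called overlapping when they shared at least 1 bp. Each of the 21 pairs of lists, counted from the shorter list except where stated, was set against 1000 circular shifts of the other list along the concatenated covered genome. The permutation p is two-sided with Benjamini-Hochberg adjustment over the 21 pairs, and the smallest value it can take is 0.002. Otx2 peaks were classed by overlap with Lim1 and Gsc peaks, and the odds of a TLE or p300 peak were compared between classes by the Mantel-Haenszel odds ratio over 10 strata of Otx2 fold enrichment. Shares have exact (Clopper-Pearson) 95% intervals. TLE peaks without p300 and p300 peaks without TLE were compared by a two-sided Fisher exact test. Fold enrichments were correlated by Spearman's rho with 100000 permutations, 10000 for alternatives. Each peak of the list named first was paired with the highest fold among the peaks of the other list that it met. Overlapping Otx2, Lim1 and Gsc peaks were also merged into regions. The regions named in the text were chosen by a rule fixed before the data were examined, namely the 10 regions of all 3 factors whose lowest fold percentile among the 3 factors was highest, and the peak of highest fold in each list. Histone marks by Otx2 class, dense windows and chromosome-only lists were added after the data were examined.

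The 29 alternatives planned before the data were examined cover a stricter −log10 q of 10, lists limited to the 2000 peaks of highest fold, overlap of at least 50% of the shorter peak, summits or midpoints within 250 bp, shifts of at most 100 kb, other strata, each chromosome left out in turn, and settings of the analyses that were not run. A further 10 were added after the data were examined. Alternatives that use shifts drew 200 of them. The procedures were tested on simulated data. With 0, 5 and 30% of 102427 simulated Lim1 peaks planted in Otx2 peaks, the planted share came back as −0.05, 5.08 and 29.93%. This is the excess over shifts as a share of the peaks that shifts leave without overlap. A planted odds ratio of 3 over 50000 simulated Otx2 peaks came back as 2.96 with strata and 4.66 without. Simulated peaks otherwise lay at random and the strata were known exactly. These checks therefore do not cover clustered peaks or differences of strength within a stratum. The 4 overlap rules gave 0 mismatches against a brute-force count in 4800 comparisons, and a planted rho of 0.38 over 20000 regions came back as 0.39. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.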

Results

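Binding of 3 transcription factors of the Spemann-Mangold organizer, 2 coregulators and 2 histone marks was mapped by ChIP-seq in whole X. tropicalis embryos at stage 10.5, with 1 library for each. Otx2 and Lim1 are head organizer activators, Gsc is an organizer repressor, TLE (Groucho) is a corepressor, and p300 is a coactivator. H3K4me1 marks enhancers and H3K27ac marks active enhancers and promoters. Otx2 had the longest list, with 194993 peaks, followed by p300 with 181254, TLE with 155638, H3K4me1 with 111281, Lim1 with 102427, H3K27ac with 91764 and Gsc with 26330. The share of peaks with a −log10 q of at least 10 was 48.1% for TLE, 32.1% for p300 and 11.5% for Gsc among the narrow lists, and 5.36% for H3K27ac, 5.27% for Otx2, 3.21% for H3K4me1 and 0.729% (747 peaks) for Lim1 among the broad lists. Every narrow list lay above every broad one, so that strength cannot be compared between these layouts. Unplaced scaffolds made up 10.6% of the covered length and held 32.8% of the Gsc peaks, 20.1% of the Lim1 peaks, 14.6% of the Otx2 peaks and 11.7% of the TLE peaks.

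The first question was which of the organizer factors occupy the same regions. In the full lists, Gsc peaks lay largely within the Otx2 and Lim1 landscape. Of the 26330 Gsc peaks, 75.6% (95% interval 75.1 to 76.1) met an Otx2 peak, against 4.12% after circular shifts, an 18.4-fold excess. Lim1 peaks were met by 54.5% of Gsc peaks, 30.4-fold more than after shifts, and Otx2 peaks by 37.2% of Lim1 peaks, 8.29-fold more. All 3 factors met at 10088 Otx2 peaks, 5.17% of that list. Separate shifts of the Lim1 and Gsc lists gave 29.0 on average and 59 at most. These shifts also break up the overlap of each pair. The excess for all 3 factors therefore includes that of the pairs and does not measure a meeting of all 3 beyond it. Each of the 21 pairs of lists exceeded its shifts, from 4.68-fold for H3K27ac with TLE to 30.4-fold for Gsc with Lim1, with an adjusted p of 0.002 by permutation for every pair, the smallest that 1000 shifts can give. With shifts of at most 100 kb, the excess was 15.7-fold for Gsc with Lim1, 7.40-fold instead of 12.4-fold for Gsc with H3K27ac, and 96.7-fold instead of 348-fold for all 3 factors. Such shifts largely keep the local density of peaks on the chromosomes. On unplaced scaffolds they can carry a peak onto another scaffold, so local density is not kept there. Otx2 and Lim1 share an input library, as do TLE and p300, and H3K4me1 and H3K27ac. The Gsc share with a Lim1 peak was 43.6% on the chromosomes and 76.8% on unplaced scaffolds.

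**Figure D1:**
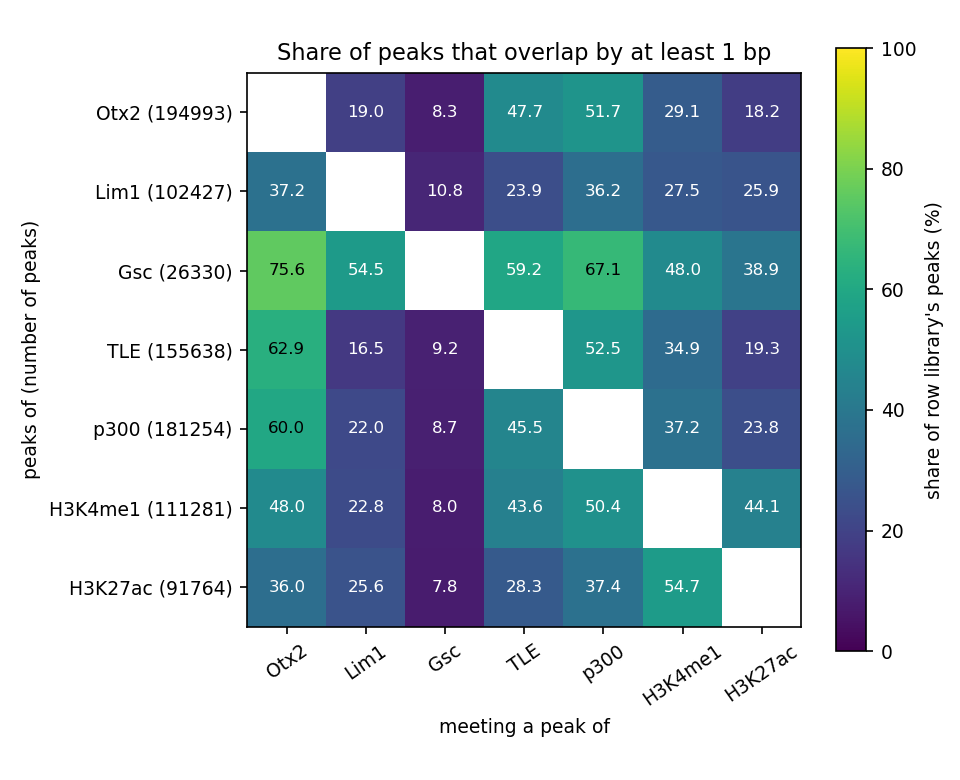
Heat map of the percent of each library's peaks (rows, number of peaks in parentheses) that overlap a peak of another library (columns) by at least 1 bp, with the diagonal left blank. The Gsc row holds the highest shares among the transcription factors, 75.6% with Otx2 and 67.1% with p300, while Gsc peaks, the shortest list, were met by 8.26% of Otx2 peaks.

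Where factors shared a region, their strengths were correlated to different degrees. Across 11052 Lim1 peaks with a Gsc peak, Spearman's rho between the fold enrichments was 0.546. Otx2 fold correlated with TLE fold at 0.465 over 93103 peaks and with p300 fold at 0.460 over 100756 peaks. Gsc fold correlated with p300 fold at 0.344 and with TLE fold at 0.148, and Lim1 fold with p300 fold at 0.269 and with TLE fold at 0.0648. On the chromosomes alone, Lim1 fold correlated with Gsc fold at 0.428, below Otx2 fold with TLE fold (0.459) and with p300 fold (0.439), and Gsc fold correlated with p300 fold at 0.210 and with TLE fold at 0.0734, and Lim1 fold with TLE fold at 0.0412. In the full lists, all 10 correlations had an adjusted permutation p of 1e-05, the smallest that 100000 permutations can give. They run across regions, which are not independent replicates. A wider peak can meet more peaks of the other list, of which the highest fold was taken, and width was not held fixed.

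The second question was which coregulators accompany Otx2 when it is bound together with Lim1, with Gsc or with both. TLE was most frequent at Otx2 peaks with Gsc but without Lim1, where 90.7% (95% interval 89.9 to 91.4) of 6012 peaks met a TLE peak. The share was 54.8% (54.2 to 55.4) of 27030 peaks with Lim1 but without Gsc, 73.7% (72.8 to 74.5) of 10088 peaks with both, and 43.1% (42.8 to 43.3) of 151863 peaks with neither. p300 was most frequent where both partners were present, at 91.7% (91.1 to 92.2), and was met by 73.2% of the peaks with Gsc alone, 72.9% of those with Lim1 alone and 44.4% of those with neither. TLE without p300 was found at 21.7% of Otx2 peaks with Gsc alone but at 3.64% of those with Lim1 alone, and p300 without TLE at 4.24% and 21.7%.

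Otx2 peaks in the highest 10% of fold met more peaks of every other library than those in the lowest 10%, 86.9% against 23.7% for TLE, and the median Otx2 fold was 5.45 with Gsc alone and 3.88 with Lim1 alone. Within strata of Otx2 fold, the odds of a TLE peak were 4.91 times higher with Gsc alone than with Lim1 alone (Mantel-Haenszel 95% interval 4.42 to 5.46, adjusted p = 7.92e-191, n = 6012 and n = 27030 peaks). The corresponding odds ratio for p300 was 0.471 (0.438 to 0.507, adjusted p = 6.72e-90, n = 6012 and n = 27030 peaks), and for TLE and p300 together 0.858 (0.799 to 0.921, adjusted p = 2.20e-05). Against Otx2 peaks with neither partner, the odds of TLE were 7.43 times higher with Gsc alone, 2.35 times with both and 1.26 times with Lim1 alone. For p300 these odds ratios were 1.46 with Gsc alone, 10.02 with both and 3.07 with Lim1 alone. Without strata the odds ratios between Gsc alone and Lim1 alone were 8.02 for TLE, 1.01 for p300 and 2.12 for both together, and with every list limited to a −log10 q of 10 or more they were 24.96, 3.44 and 5.74. Among the 2000 peaks of highest fold, that for p300 was 0.0995. The ratio of 0.858 also turned to 1.68 within strata of Otx2 width and to 1.92 with the Lim1 list shortened to the length of the Gsc list. Over the other settings, the TLE ratio of 7.43 against neither partner ranged from 2.38 at that threshold to 12.9 without strata, and the p300 ratio of 10.02 from 5.15 within strata of fold and width to 19.2 at that threshold. The TLE ratio of 1.26 turned to 0.876 within strata of Otx2 width and to 0.0794 at that threshold, and the p300 ratio of 3.07 turned to 0.397 at that threshold. The p300 ratio of 1.46 turned to 0.808 within strata of fold and width and to 0.195 among the 2000 peaks of highest fold. In the same settings the TLE ratio of 2.35 was lost, at 0.974 (0.920 to 1.03) and 0.787 (0.501 to 1.24), with intervals that include 1. The threshold held for the partner lists too: of its 111 Otx2 peaks with a strict Lim1 but no strict Gsc peak, 47 met a weaker Gsc peak, and of its 8962 with no strict partner, 3352 met no Lim1 and no Gsc peak at all.

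**Figure D2:**
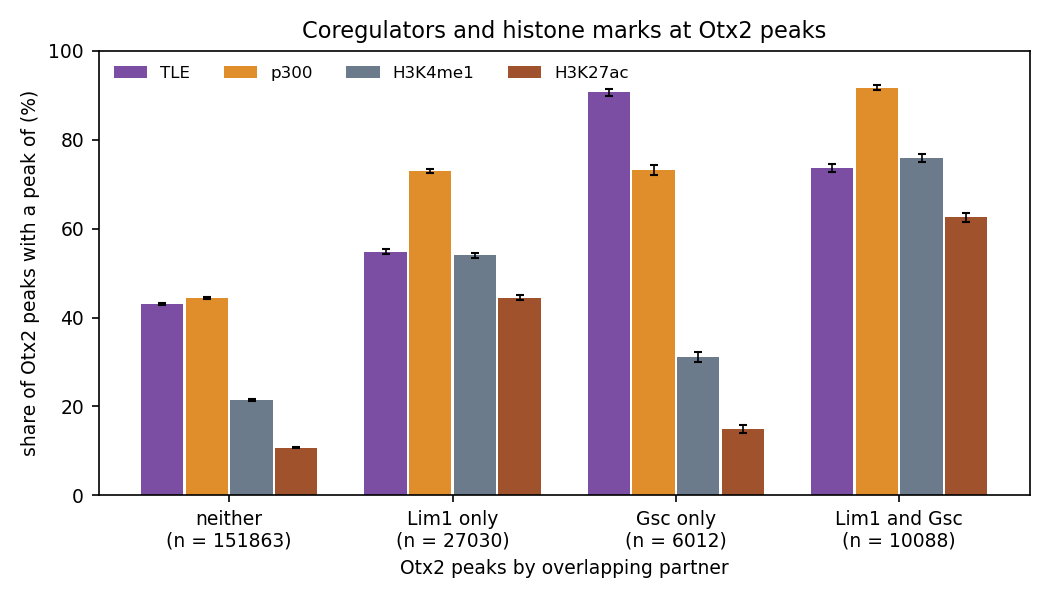
Bars give the percent of Otx2 peaks that meet a TLE, p300, H3K4me1 or H3K27ac peak, for Otx2 peaks that overlap neither partner, Lim1 only, Gsc only or both, with the number of peaks under each class and exact 95% intervals as error bars. With Gsc only, TLE reached 90.7% and H3K27ac 15.0%, and with Lim1 only, TLE was at 54.8% and H3K27ac at 44.4%.

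The histone marks at the same peaks were a comparison added after the data were examined. H3K27ac was met by 62.5% of Otx2 peaks with both partners, 44.4% (43.8 to 45.0) of those with Lim1 alone, 15.0% (14.1 to 15.9) of those with Gsc alone and 10.8% of those with neither. H3K4me1 was met by 75.9, 54.0, 31.1 and 21.5% of the same classes. In that order, their median widths were 344, 216, 272 and 126 bp, and 40.5, 22.1, 11.4 and 11.6% lay on unplaced scaffolds. The higher shares with Gsc alone than with neither were not kept within strata of Otx2 width. There the odds ratios were 0.766 (0.711 to 0.826) for H3K27ac and 0.916 (0.864 to 0.971) for H3K4me1. Within strata of Otx2 fold, Otx2 peaks with Gsc alone had lower odds than those with Lim1 alone of H3K27ac, with an odds ratio of 0.222 (0.205 to 0.239), and of H3K4me1, with an odds ratio of 0.312 (0.293 to 0.332). These ratios were 0.511 and 0.743 with the Lim1 list shortened to the length of the Gsc list, and 0.361 and 0.577 with summits or midpoints within 250 bp. With every list limited to a −log10 q of 10 or more, which left n = 879 peaks in the class with Gsc and n = 111 in the class with Lim1, the H3K27ac odds ratio was 0.623 and did not pass the test (adjusted p = 0.222), and that of H3K4me1 turned to 1.55 (adjusted p = 0.299).

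Over all peaks of each factor in the full lists, Gsc peaks carried both marks most often, but with every list limited to a −log10 q of 10 or more the share was 32.5% for Lim1 and 17.7% for Gsc. In the full lists, both marks were met by 32.6% (32.0 to 33.2) of Gsc peaks, 18.8% of p300 peaks, 16.6% of Lim1 peaks, 15.1% of TLE peaks and 13.8% of Otx2 peaks. The excess over shifts was 19.7-fold for Gsc, 9.82-fold for p300, 9.39-fold for Lim1, 7.47-fold for TLE and 7.05-fold for Otx2, each with an adjusted p of 0.002 by permutation. Neither mark was met by 45.7% of Gsc peaks and by 66.5% of Otx2 peaks. On the chromosomes alone 28.9% of Gsc peaks met H3K27ac, against 59.4% on unplaced scaffolds.

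The third question was how regions of the corepressor TLE and of the coactivator p300 differ. They coincided often: 52.5% of TLE peaks met a p300 peak, 11.2-fold more than after shifts, and 45.5% of p300 peaks met a TLE peak. Shared peaks met transcription factors and marks more often than unshared ones. They were also stronger, with a median fold of 7.58 against 4.98 for TLE and 5.36 against 4.23 for p300. In no alternative, strata of the peak's own fold among them, did an odds ratio of shared against unshared peaks change direction. The lowest was 1.14, for H3K27ac at p300 peaks. Peak width was not held fixed. Of the 81679 TLE peaks with p300, 85.9% met Otx2, 28.6% Lim1, 15.3% Gsc, 51.5% H3K4me1 and 30.7% H3K27ac. Of the 73959 TLE peaks without p300, 37.5% met Otx2, 3.22% Lim1, 2.46% Gsc, 16.5% H3K4me1 and 6.76% H3K27ac. The p300 peaks with TLE met these lists in 85.2, 28.0, 14.6, 51.1 and 29.2% of cases, and those without TLE in 39.0, 17.002, 3.70, 25.5 and 19.4%.

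Between peaks of TLE alone and the 98814 peaks of p300 alone, Lim1 and H3K27ac differed most in the full lists, but with every list limited to a −log10 q of 10 or more the odds ratios were 0.0214 for Lim1, 0.0571 for H3K4me1 and 0.0721 for H3K27ac. In the full lists, Lim1 was met by 3.22% of TLE-only peaks and 17.002% of p300-only peaks, an odds ratio of 0.163 (0.156 to 0.170), and H3K27ac by 6.76% and 19.4%, an odds ratio of 0.302 (0.292 to 0.312). H3K4me1 was met by 16.5% and 25.5%, an odds ratio of 0.576 (0.563 to 0.590). Otx2 and Gsc gave odds ratios of 0.937 and 0.657 by Fisher's exact test, with adjusted p of 1.09e-10 and 7.01e-49. By the same exact test on the chromosomes alone these were 0.996 (adjusted p = 0.791) and 0.994 (adjusted p = 0.861). The exact test for Otx2 turned to 1.25 (adjusted p = 4.31e-09) with every list limited to a −log10 q of 10 or more and to 2.24 (adjusted p = 2.84e-15) among the 2000 peaks of highest fold, where that for Gsc turned to 1.34 (adjusted p = 0.0518). With the limit on q, the exact test for Gsc gave 0.297 (adjusted p = 3.20e-66).

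**Figure D3:**
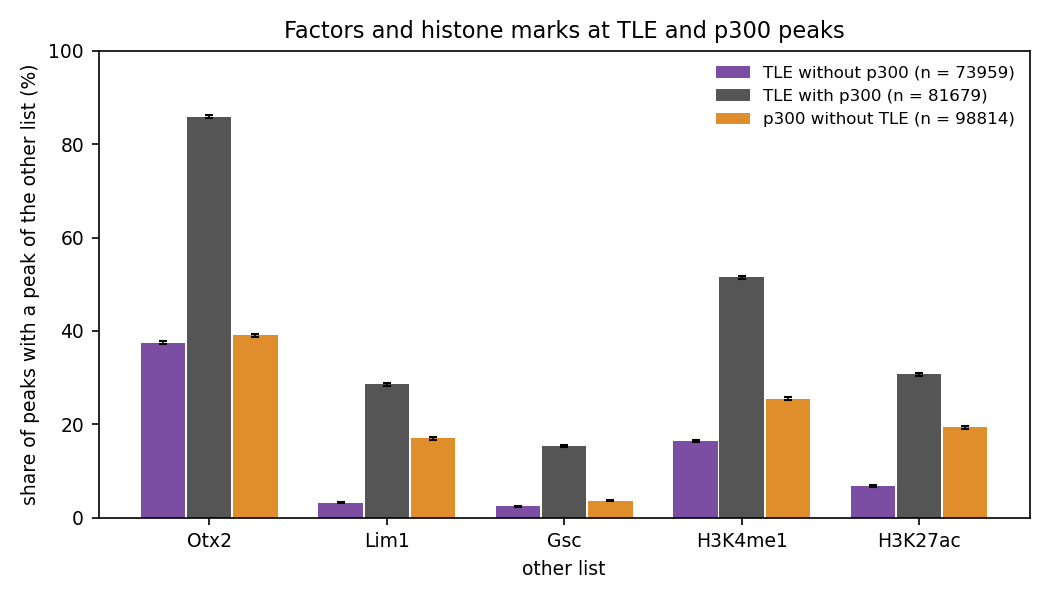
Bars give the percent of TLE peaks without p300, TLE peaks with p300 and p300 peaks without TLE that meet a peak of each other library, with exact 95% intervals as error bars and numbers of peaks in the key. TLE-only peaks met Lim1 in 3.22% and H3K27ac in 6.76% of cases, below the 17.002% and 19.4% of p300-only peaks.

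Merging the Otx2, Lim1 and Gsc peaks gave 263056 regions, of which 10108 held all 3 factors. Of these, 71.6% also met TLE and p300, and 42.5% met peaks of all 7 libraries. They lay on unplaced scaffolds in 40.1% of cases. TLE was rare at regions without an Otx2 peak: it was met by 3.19% of the 63026 regions of Lim1 alone and 7.75% of the 4630 of Gsc alone. The share was 11.2% for the 1233 regions of Lim1 with Gsc, 43.1% for the 151863 of Otx2 alone and 90.9% for the 5993 of Otx2 with Gsc. Their median widths were, in that order, 77, 56, 174, 126 and 275 bp. Neither width nor strength was held fixed, so these shares do not show that TLE depends on Otx2. After shifts, 3.71% of all Lim1 peaks and 3.42% of all Gsc peaks met TLE. p300 was met by 11.2% of the regions of Lim1 alone and 10.7% of those of Gsc alone, but by 51.6% of those of Lim1 with Gsc.

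The 10 regions of all 3 factors chosen by the fixed rule were 116 to 259 bp wide, and each met peaks of all 7 libraries. Of these, 8 lay on unplaced scaffolds. The remaining regions lay on chromosome 7 at 89101856 to 89102024, with folds of 19.2 for Otx2, 16.6 for Lim1, 27.2 for Gsc and 40.6 for TLE, and on chromosome 9 at 80295847 to 80296025, with folds of 15.4, 16.6, 32.1 and 20.8. The highest fold of the Otx2 list (21.9) and of the Lim1 list (21.8) lay at positions 1 to 116 and 1 to 104 of scaffold 481, that of Gsc (37.8) on scaffold 434 at 26110 to 26222, that of TLE (40.6) at the chromosome 7 region, and those of H3K4me1 (14.7) and H3K27ac (16.0) at the start of scaffold 784. The highest p300 fold (42.8, scaffold 555 at 95471 to 95640) met a peak of Otx2 and of no other library.

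On the chromosomes, regions of all 3 factors were found in 28.2% of 12731 windows of 100 kb, with a mean of 0.476 per window. A stretch of 300 kb on chromosome 8, from 97700001 to 98000000, held 38 of them and was chosen after the values were seen. Of these 38 regions, 37 met TLE, 38 p300, 37 H3K4me1 and 35 H3K27ac. Their median fold was 4.50 for Otx2, 4.83 for Lim1, 6.34 for Gsc, 9.07 for TLE and 7.30 for p300. Peaks of factors and marks had nearly the same ends at some regions, as at 97951449 to 97953499 for Otx2 and 97951403 to 97953576 for H3K27ac. Sequence enriched alike in every library was not tested here, and the build is not known. The stretch is therefore not shown to be a site of dense binding.

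**Figure D4:**
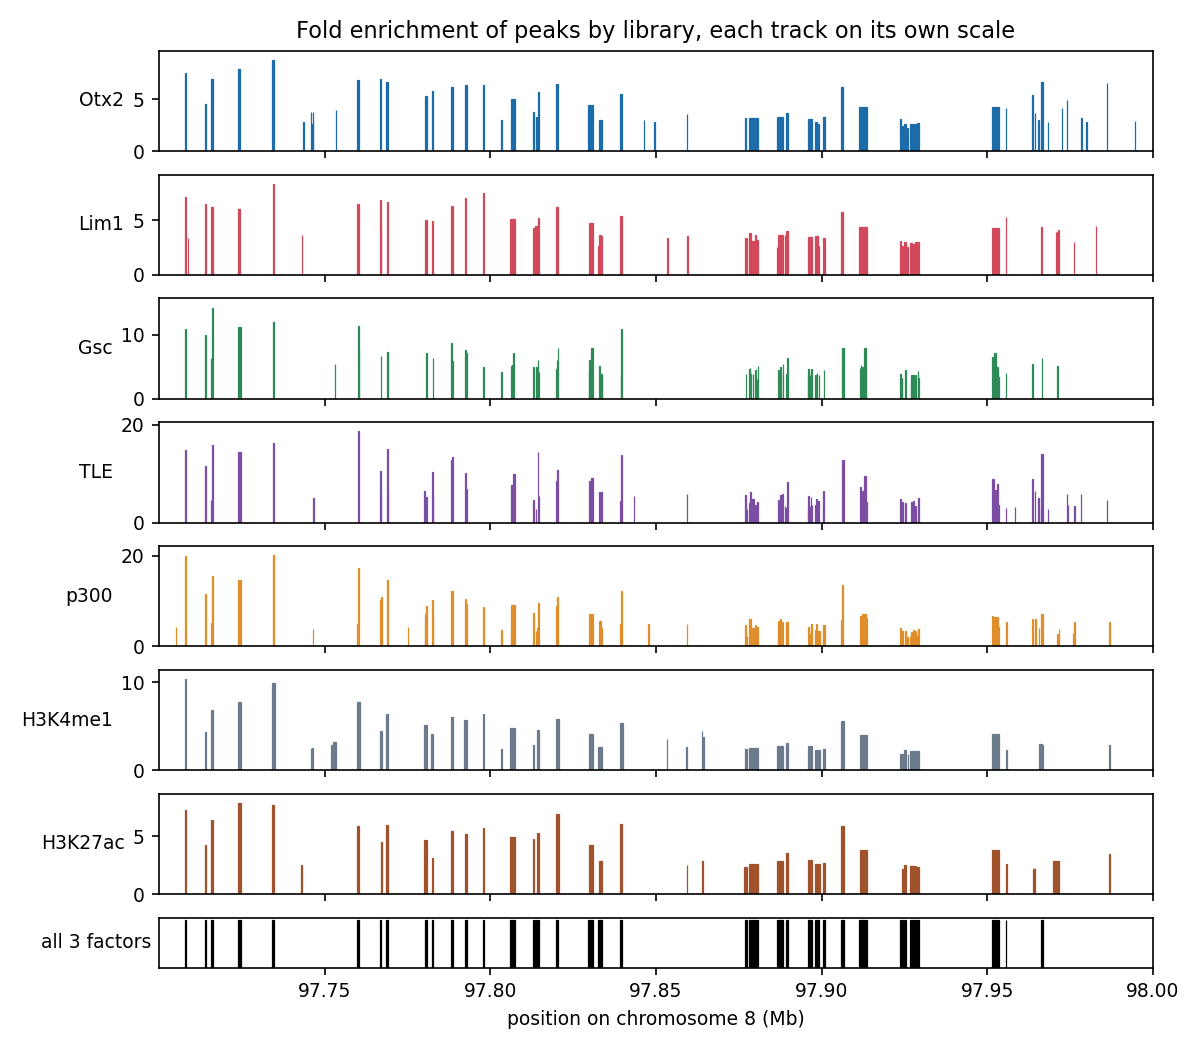
Peaks of the 7 libraries along chromosome 8 from 97700001 to 98000000, each bar spanning a peak's start and end with its fold enrichment as height on a scale of its own per track, and the regions of all 3 transcription factors in the bottom track. The 38 regions of Otx2, Lim1 and Gsc mostly coincide with TLE, p300, H3K4me1 and H3K27ac peaks. Whether sequence enriched alike in every library gives these peaks was not tested.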

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

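Settings with strata of Otx2 fold and width, the chromosomes alone, the strict threshold on the chromosomes and a Lim1 list shortened to the length of the Gsc list, strata of the peak's own fold, and every comparison of marks by partner, were chosen after the data were examined. No paired analysis was possible because each antibody has 1 library. The alternatives on gene lists, motifs and transcription start sites were not run, and 1 value was undefined (the overlap of all 3 factors among the 2000 peaks of highest fold, where no shift gave any). The direction and the side of the threshold were kept in 351 of 351 values for overlaps and 20 of 20 for correlations (whose sizes moved by more than 1.5 times in some settings, as with local shifts, which gave 15.7-fold for Gsc with Lim1), and in 118 of 120 for marks, 68 of 75 for TLE against p300, 209 of 240 for coregulators by partner and 144 of 160 for marks by partner. In both sets by partner, 10 settings per result left out 1 chromosome and 10 were other alternatives. Every change in these sets fell among the other alternatives, so the pooled counts overstate how stable the results were. The odds ratio of TLE between Otx2 peaks with Gsc alone and with Lim1 alone ranged from 3.94 to 69.3 over the other alternatives and from 4.70 to 4.97 when each chromosome was left out. Below, "Gsc/Lim1" sets Otx2 peaks with Gsc alone against those with Lim1 alone, and "Lim1/neither", "Gsc/neither" and "both/neither" are formed likewise. The strict threshold held for every list, so its class with Lim1 (111 peaks, 81 on the chromosomes) lacked a strict Gsc peak, but 47 of the 111 met a weaker one, and of its 8962 peaks with neither strict partner, 3352 met no Lim1 and no Gsc peak at all. The cause of the other changes was not tested.

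At a −log10 q of 10 or more, the odds ratios for TLE were 0.0794 (Lim1/neither) and 1.18 (both/neither), for p300 0.397 (Lim1/neither) and 3.44 (Gsc/Lim1), and for TLE with p300 0.270 (Lim1/neither) and 5.74 (Gsc/Lim1). On the chromosomes at that threshold, TLE gave 0.0593 (Lim1/neither) and 1.03 (both/neither), p300 gave 0.297 (Lim1/neither), 1.21 (Gsc/neither) and 4.15 (Gsc/Lim1), and TLE with p300 gave 0.218 (Lim1/neither) and 7.62 (Gsc/Lim1). With the 2000 peaks of highest fold, TLE gave 0.249 (Lim1/neither) and 0.787 (both/neither), p300 gave 1.64 (Lim1/neither) and 0.195 (Gsc/neither), and TLE with p300 gave 1.65 (Lim1/neither), 1.26 (Gsc/neither) and 0.495 (Gsc/Lim1). With strata of width, TLE gave 0.876 (Lim1/neither) and TLE with p300 gave 1.68 (Gsc/Lim1). With strata of fold and width, TLE gave 0.751 (Lim1/neither) and 0.974 (both/neither), and p300 gave 0.808 (Gsc/neither). Without strata, Gsc/Lim1 was 1.01 for p300 and 2.12 for TLE with p300. With summits or midpoints within 250 bp, TLE with p300 gave 1.06 (Gsc/Lim1). With the shortened Lim1 list, TLE gave 0.881 (Lim1/neither), and Gsc/Lim1 was 1.19 for p300 and 1.92 for TLE with p300.

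For the marks by partner, the strict threshold gave 1.42 (Lim1/neither) and 1.55 (Gsc/Lim1) for H3K4me1 and 1.77 (Lim1/neither) and 0.623 (Gsc/Lim1) for H3K27ac. On the chromosomes at that threshold, H3K4me1 gave 1.26 (Lim1/neither) and 1.18 (Gsc/Lim1), and H3K27ac gave 1.39 (Lim1/neither), 0.654 (Gsc/neither) and 0.474 (Gsc/Lim1). With the 2000 peaks of highest fold, Gsc/neither was 1.86 for H3K4me1 and 1.17 for H3K27ac, and Gsc/Lim1 was 0.433 for H3K27ac. Gsc/neither was 0.916 for H3K4me1 and 0.766 for H3K27ac with strata of width, and 0.909 and 0.827 with strata of fold and width. For H3K27ac without H3K4me1, the 2000 TLE peaks of highest fold gave 1.02-fold and the 2000 p300 peaks 0.489-fold over shifts.

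Between TLE-only and p300-only peaks, the odds ratio for Otx2 was 1.25 at the strict threshold, 1.01 with overlap of at least 50% of the shorter peak, 2.24 with the 2000 peaks of highest fold, 1.02 with strata of the peak's own fold and 0.996 on the chromosomes, and that for Gsc was 0.297 at the strict threshold, 1.34 with the 2000 peaks of highest fold and 0.994 on the chromosomes. Read depth is not known from peak lists, so a missing peak shows only that none passed the authors' threshold.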

Other observations

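Dense groups of regions with peaks of all 3 transcription factors differed in fold, as values seen only after the data were examined. On chromosome 8 the windows of 100 kb from 97700001, 97800001 and 97900001 held 13, 15 and 10 such regions, with median Otx2 folds of 6.64, 3.26 and 3.74. On chromosome 2 the windows from 102000001 and from 102100001 held 10 and 13, with median folds between 1.55 and 2.12 in all 7 libraries. For Otx2 these medians were 1.75 and 1.84, within the lowest 10% of its list by fold (1.41 to 2.87). Low folds that were alike in factors and marks do not show binding there, and their cause was not tested. Further windows with 10 or more lay on chromosome 7 from 18600001 (12 regions, median Otx2 fold 4.67), chromosome 6 from 82800001 (10 regions, 3.35) and chromosome 9 from 45600001 (10 regions, 3.42).

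Of the tests that follow, those on strength, width and unplaced scaffolds for TLE with Gsc, on Otx2 peaks of unplaced scaffolds, and on width and the shared input for strict peaks were chosen after the results they bear on had been seen.

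TLE was more frequent at Otx2 peaks with Gsc alone than with Lim1 alone. Neither stronger nor wider Otx2 peaks nor unplaced scaffolds account for the whole difference, since the odds ratio was 8.02 without strata and still 4.91 within strata of fold, 4.78 (4.27 to 5.35) within strata of fold and width, and 5.86 (5.14 to 6.67) on the chromosomes. Nor does the length of the Lim1 list alone, since shortening it to the number of Gsc peaks gave 4.90 (4.52 to 5.32). The class with Gsc then held 10212 peaks instead of 6012, because peaks that met only a dropped Lim1 peak entered it. Equal length does not equalise strength, which cannot be compared between the 2 layouts, so weaker Lim1 peaks are not excluded as a part of the cause. A candidate explanation is that Gsc brings TLE to these regions, in which case TLE signal may follow Gsc signal. The test set beforehand was that the partial rank correlation of Gsc fold given Otx2 fold be higher with TLE fold than with p300 fold. It was run at the 3768 peaks of this class on the chromosomes that met both a TLE and a p300 peak. There it was met (difference 0.0983, 0.0547 to 0.138), but only because Gsc fold ran against p300 fold (−0.101). The partial correlation with TLE fold was −0.00254 (−0.0370 to 0.0275). A link with TLE itself was then required, a condition added after these values were seen, so the hypothesis stays undecided. Because every peak in the test had TLE, it does not show whether the presence of TLE follows Gsc.

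The regions of all 3 factors lay on unplaced scaffolds more often than the covered length would give, and the strongest were narrow. A candidate explanation for the scaffolds is sequence enriched alike in every library. As written, its test failed if at least 1 library was met less often there, with intervals that do not meet. TLE was: 38.8% (38.2 to 39.3) of Otx2 peaks there met TLE against 49.3% on the chromosomes. The rule applied asked for more than 1 lower library, and the shares with the other 5 libraries were higher, so the explanation was left open. Of the regions of all 3 factors themselves, fewer met TLE (65.7 and 78.6%) and p300 (90.1 and 93.2%) there. More of them met H3K4me1 (84.5 and 70.7%) and H3K27ac (72.4 and 57.6%), so the libraries did not go alike. A candidate explanation for the top 1% of regions (102) is sharp signal of technical origin in every library, which would narrow the histone peaks too. H3K4me1 peaks there were narrower than at the other regions (medians 339 and 559 bp, difference −220 bp, −239 to −143, p = 0.0002 by permutation, the smallest that 10000 can give), and on the chromosomes alone the difference was −171.5 bp (−222 to −100.0, p = 0.0008), which argues against scaffolds as the whole cause. The widths cannot decide on sharp signal, because each region was given its widest H3K4me1 peak and region width was not held fixed. A narrower region can meet fewer and narrower peaks. The 10 regions chosen by the fixed rule were 116 to 259 bp wide, against a median of 406 bp for the regions of all 3 factors. Small accessible elements with narrow marked flanks could give the same widths, and no biological explanation was tested.

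At a −log10 q of 10 or more, Otx2 peaks with a strict Lim1 but no strict Gsc peak met TLE less often than those with neither strict partner. Unplaced scaffolds do not account for this, since the odds ratio was 0.0593 (0.0346 to 0.102) on the chromosomes. Against the full lists, the share was low at the 64 such peaks that met no Gsc peak at all: 29.7% (18.9 to 42.4) of them met TLE, against 83.1% of 3352 strict Otx2 peaks with neither partner and 91.3% of 367 with a strict Lim1 and a Gsc peak, and their lower median width (95.5 and 201 bp) does not account for the whole, since the odds ratio within strata of width was 0.248 (0.118 to 0.520). A candidate explanation is background of the input that Otx2 and Lim1 share, which would lower the share with every library of another input: 37.5% (25.7 to 50.5) of the 64 met p300 against 86.5% of the 3352 and 96.5% of the 367, with an odds ratio of 0.134 (0.0749 to 0.239) against the 3352 within strata of width, but those for H3K4me1 (met by 16 of the 64 and by 37.8%) and H3K27ac (20.3 and 18.9%) were 1.42 (0.733 to 2.77) and 3.45 (1.63 to 7.29). As written, the test asked only for a lower share with p300, with intervals that do not meet, and this was met. Conditions were added to it: a p300 odds ratio below 1 within strata of width, and neither histone mark met more often. H3K27ac went the other way within strata of width, and the interval for H3K4me1 includes 1. The shared input therefore stays open for the 64 peaks, as does Otx2 and Lim1 binding without coregulators.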
